A study of Medicago truncatula with 4 samples.

How the data were processed

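Small RNA libraries had been made from total RNA of roots with a TruSeq small RNA kit after enrichment of the small RNA fraction, per the labels' protocols. The authors deposited, for each library, a table of distinct sequences and the raw count of reads of each sequence, without normalization, per the file headers and the values. All 4 tables list the same 6762531 sequences of 18 to 25 nt, with a count of 0 where a library lacks a sequence. How adapters were removed, which filters were applied and whether reads were matched to a genome is not given in the sources used here. Only 9 reads in all 4 libraries matched 5.8S ribosomal RNA, so the share of ribosomal fragments cannot serve here as a sign of RNA quality. No molecular identifiers are named in the labels, so copies made by PCR are counted as reads.

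Libraries were grouped by the sample titles into rdr6.1 and WT, with 2 libraries each, and numbered as in the titles. The labels call the rdr6.1 lines siblings and letter the libraries of each genotype A and B, but do not say whether libraries of the same letter are paired families; they were treated as unpaired. Primer index 1 was used for replicate 1 and primer index 3 for replicate 2 of both genotypes. The file names of the rdr6.1 libraries carry a different sequencing lane tag from those of the WT libraries, so lane and genotype cannot be told apart. Replicates differed beyond sampling noise: over sequences with at least 20 reads, the mean chi-square per sequence was 6.7 between the rdr6.1 libraries and 10.9 between the WT libraries. For a given relative difference a chi-square grows with read count. Abundant sequences therefore weigh most in this mean, which does not describe a typical sequence. Depth was 4948844 to 5851415 reads per library.

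The comparison, its tests, the lists, the rule for named sequences and most alternatives were fixed before the data were examined. Sequences were the unit of the test, although lengths to 26 nt had been planned and the tables end at 25 nt. They were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 25493 sequences holding 47.1% of the reads. Counts were scaled with TMM factors on library totals and tested with the quasi-likelihood test (glmQLFit and glmQLFTest) of edgeR for genotype alone, with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. CPM values are counts divided by library totals times these factors. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic, and 95% intervals from its degrees of freedom. Counts of miRNA families were summed over exact mature sequences, and those of tasiARF over 39 sequences containing a fixed 15-nt core, then tested in the same fit. Of 20 conserved families fixed, 17 had reads and 12 passed the filter. Of 5 trigger families 3 passed; the fixed sequences of miR2109 were not seen and miR1509 had 3 reads. Set tests used camera and fry of limma 3.58.1 on lists of at least 5 sequences. The edgeR step was tested on simulated counts for the 25493 sequences with 200 changed, and the sequence functions on constructed sequences.

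Named sequences were those of the fixed lists and, among sequences past the threshold with a mean of at least 10 CPM in a genotype and libraries that did not overlap, the 10 with the largest fall and the 10 with the largest rise (7 qualified). Any other named sequence is said to have been chosen after its values were seen.

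Alternatives were RLE factors, total counts, scaling to the conserved miRNA reads, DESeq2 1.42.0, no abundance filter, a 2-fold minimum, the replicate number as a block, each library left out in turn, miRNA variants of up to 2 nt length change at the 3' end, and other denominators for the size classes. No reference genome was used here. The planned tests of small RNA loci, phased loci and lists by gene annotation (NBS-LRR genes, auxin response factors, transposons, organelle, tRNA and ribosomal fragments and others) were therefore not run, and sequences are given without coordinates. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.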

Results

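Small RNAs were sequenced from roots of 10-day-old plants of Medicago truncatula, a model legume, that carried the rdr6.1 mutation or were wild type (WT). RDR6 is an RNA-dependent RNA polymerase that copies cleaved transcripts into double-stranded RNA, from which Dicer-like enzymes cut phased and trans-acting siRNAs. There were 4 libraries, 2 from sibling rdr6.1 lines and 2 from the corresponding WT plants; the labels do not say whether libraries of the same replicate number are paired. The rdr6.1 libraries held 5834655 and 5143010 reads of 18 to 25 nt, and the WT libraries held 4948844 and 5851415. These reads fell on 6762531 distinct sequences, and 81.5% to 83.0% of the sequences seen in a library were seen once. The 2 most abundant sequences, which overlap along miR166, took 20.3% to 29.4% of the reads of a library. A sequence with 3 reads, the limit that a count of 0 allows, corresponded to 0.487 to 0.625 CPM, read counts scaled to library totals times TMM factors; intervals and limits of this kind cover counting error only. The labels do not describe the plants pooled for a library, so p-values measure the spread between these libraries.

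The first question was which small RNAs depended on RDR6. Of 25493 sequences abundant enough to test, 370 fell and 14 rose in rdr6.1. The fallen sequences were a median of 12.4-fold lower, or 11.9-fold with the 15 that had no reads in rdr6.1 set to 3 reads over both libraries; a further 84 rested on 1 to 3 reads in rdr6.1. The 271 with more than 3 reads in rdr6.1 spanned log2 fold changes of -5.49 to -1.94. The 370 together made up 0.707% and 0.863% of the reads in the WT libraries, against 0.099% and 0.058% in the rdr6.1 libraries, a difference for which they had been selected. The 370 sequences formed 258 groups that shared a stretch of at least 15 nt on either strand, so that 197 stood alone and the largest group held 9. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. For all 384 called sequences, both libraries of a genotype lay on the same side of both libraries of the other. For a sequence not chosen by its values, chance gives that separation with probability 0.33. The 384 were called on these same libraries, so their separation follows from the selection and adds no support. The counts depended on WT replicate 1, without which 639 sequences fell and 215 rose, and on the abundance filter, without which 1005 fell and 262 rose. Of the 384 calls, 227 remained without WT replicate 2 and 238 without rdr6.1 replicate 1.

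Most fallen sequences were of 21 nt, the length of phased siRNAs and most miRNAs. Among 2320 tested 21-nt sequences 289 fell and 5 rose, which is 12.46% fallen, and the class supplied 78.1% of the fallen sequences while making up 9.1% of those tested (Fisher's exact test, two-sided, odds ratio 40.6, p = 8.81e-229; overlapping sequences are not independent). The sequences also come from the same 4 libraries, so this p-value does not measure the spread between libraries. The test was not matched on abundance. Of 1638 tested 22-nt sequences 38 fell and 6 rose. In the 24-nt class, the length of heterochromatic siRNAs, 4 of 18669 tested sequences fell, and the median log2 fold change was 0.00. That class made up 73.2% of the tested sequences, from which the TMM factors were taken. Its median near 0 therefore does not show that the class was unchanged. The 18-nt, 19-nt, 20-nt, 23-nt and 25-nt classes contributed 7, 12, 13, 6 and 1 fallen sequences. As shares of the sequences tested in each class these were 2.57%, 3.88%, 2.77%, 0.44% and 0.22%, against 2.32% at 22 nt. A competitive set test on length classes (camera) placed the 21-nt class lower than the other sequences, with adjusted p = 4.93e-21 at the preset correlation and adjusted p = 0.0518 with an estimated correlation. In simulated data for this comparison, 37 of 50 sequences changed 8-fold and 1 of 50 changed 2-fold were recovered, so 2-fold differences were mostly not detectable with 2 libraries per genotype at this depth and spread.

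**Figure D1:**
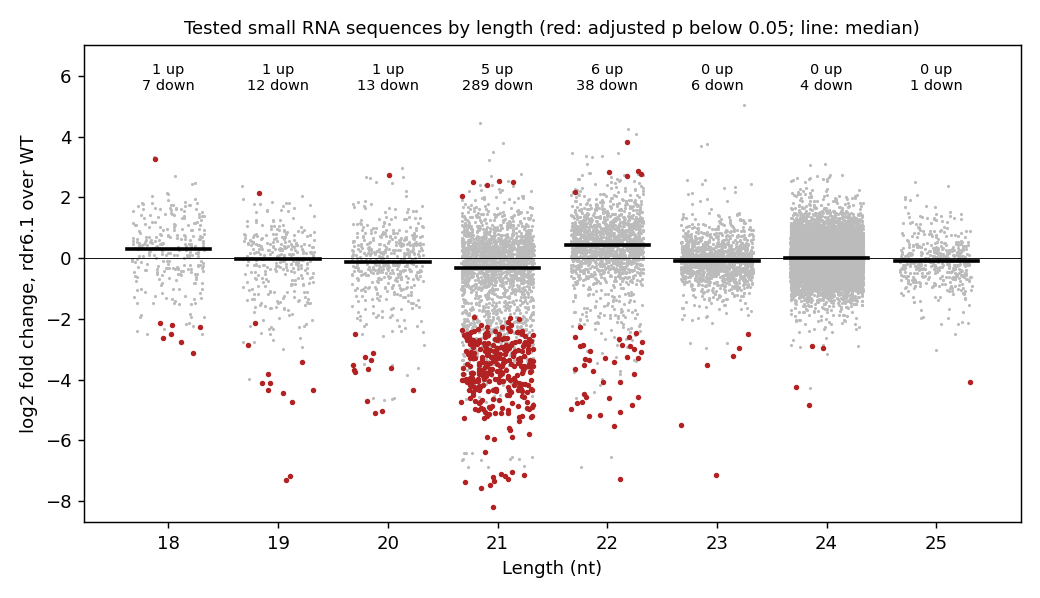
Log2 fold change of rdr6.1 over WT (vertical axis) for each of the 25493 tested sequences by length in nt (horizontal axis). Red points passed an adjusted p of 0.05, grey points did not, and black lines are medians; 289 of the 370 fallen sequences lie in the 21-nt column, whereas the 24-nt column, with 18669 sequences, holds 4.

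The fallen sequences ranged from abundant to rare. Among the 10 with the largest falls at a mean of at least 10 CPM, 2 stood well above the others in WT. CTTGTGGAACGGACAATGCCT stood at 83.9 ± 7.78 CPM in WT and 2.58 ± 2.77 CPM in rdr6.1 (SD, n = 2 each), 31.1-fold lower (log2 fold change -4.96, SE 0.71, edgeR adjusted p = 0.0161). TCGTCATGAAAGTCAAGGGC stood at 82.5 ± 5.60 and 3.12 ± 0.873 CPM (SD, n = 2 each), 26.1-fold lower (log2 fold change -4.70, SE 0.45, edgeR adjusted p = 0.0138). TCGTTATGAAAGTAAAGGGCT fell 31.7-fold, from 28.9 CPM. The 23-nt sequence AGCCGATGATGACAAAATCAAAT had the largest fitted fall of the 10, 45.0-fold, from 25.8 ± 9.01 to 0.556 ± 0.0973 CPM (SD, n = 2 each). It had 3 reads in each rdr6.1 library, so the small SD there reflects library scaling of equal counts. Its 6 reads against 273 in WT gave a ratio of 45.7, with a 95% exact binomial counting interval of 20.7 to 126. That interval overlaps those of the other named falls, so the order among the 10 is not settled. The 22-nt sequences AACCGCGGAAACCGAAAAGCTC and AATTCGCTCGGTCTGTTATGGG fell 36.9-fold and 27.6-fold, from 39.5 and 36.9 CPM in WT. The remaining 4, all of 21 nt, were TTTGGAGATATTGTCGGTTGA (36.9-fold lower), CGAGGATCGTTTCAGGGACAA (34.2-fold lower), AATCCGGAGAAACAAGAGCTG (34.1-fold lower) and CTAGAGCACTTGGAGGACTTC (27.7-fold lower), with WT means of 10.0 to 17.4 CPM. CGAGGATCGTTTCAGGGACAA had 3 reads in rdr6.1 against 108 in WT, a ratio of 36.2 with a 95% exact binomial counting interval of 12.1 to 178. The fall of AACCGCGGAAACCGAAAAGCTC did not pass in DESeq2 (adjusted p = 0.252). Without the abundance filter it did not pass either, nor did CTTGTGGAACGGACAATGCCT, AATTCGCTCGGTCTGTTATGGG and TCGTCATGAAAGTCAAGGGC (edgeR adjusted p = 0.655 for each). The named falls that did not pass without the filter were the more abundant ones. Their mean log2 CPM was 4.28 to 5.45, against 2.45 to 3.92 for the named falls that passed. Why the more abundant falls did not pass was not tested. Leaving out a library moved the size of 6 of the 10 falls by over 1.5 times. Without rdr6.1 replicate 1, which leaves 3, 1, 1 and 1 reads in rdr6.1, the log2 fold changes were -7.03 for CTTGTGGAACGGACAATGCCT, -7.33 for AATTCGCTCGGTCTGTTATGGG, -6.98 for TCGTTATGAAAGTAAAGGGCT and -6.25 for TTTGGAGATATTGTCGGTTGA. Without rdr6.1 replicate 2 they were -4.20, -4.01, -4.28 and -4.70, and that of TTTGGAGATATTGTCGGTTGA was -4.51 without WT replicate 2. AACCGCGGAAACCGAAAAGCTC and CGAGGATCGTTTCAGGGACAA had 0 reads in rdr6.1 replicate 2, so their fold sizes rest on replicate 1 (log2 fold changes of -4.33 and -4.30 without replicate 2).

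Chosen after their values were seen, the most abundant fallen sequences were TAGTAGTAGAACATCATTTGA, which went from 549 ± 387 CPM in WT to 34.9 ± 11.9 CPM in rdr6.1 (SD, n = 2 each; 15.7-fold lower), and GGAGAATTCGCTCGGTCTGTT, which went from 497 ± 227 to 19.9 ± 16.6 CPM (SD, n = 2 each; 24.8-fold lower). The overlapping pair CAGAATTCCCAGTTGGACTAG and ACAGAATTCCCAGTTGGACTA, offset by a single base, fell 8.02-fold and 6.42-fold. Their edgeR adjusted p-values were 0.0246 and 0.0240, and those of TAGTAGTAGAACATCATTTGA and GGAGAATTCGCTCGGTCTGTT were 0.0207 and 0.0194. The log2 fold change of TAGTAGTAGAACATCATTTGA, -3.97, was -4.56 without WT replicate 1 and -2.98 without WT replicate 2, and that of GGAGAATTCGCTCGGTCTGTT, -4.63, was -5.95 and -3.97 without rdr6.1 replicates 1 and 2. None of these 4 passed without the abundance filter, and ACAGAATTCCCAGTTGGACTA did not pass without rdr6.1 replicate 1 (edgeR adjusted p = 0.0616).

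Of the 14 risen sequences, 6 were of 22 nt and 5 of 21 nt, and 7 reached a mean of 10 CPM. CATTGGATAGAATTAAAGGCCT, of 22 nt, was 7.29-fold higher in rdr6.1, at 13.4 ± 0.743 against 1.81 ± 0.221 CPM (SD, n = 2 each; log2 fold change 2.87, SE 0.40, edgeR adjusted p = 0.0152). CGGGATGAATGATGGATGAGAT and TGGGGATATCGGGGTAGACAAC, also of 22 nt, were 7.13-fold and 4.50-fold higher. The others were CTTCAAGGACGATCACTCGCT (5.73-fold higher), TCGGATCTTCGGTGATGGATC (5.63-fold higher), AGAATGCATTGGATGGATG (4.44-fold higher) and ACAGTAGTAGAAGCCTTGCCT (4.08-fold higher), with means of 10.2 to 48.1 CPM in rdr6.1. CTTCAAGGACGATCACTCGCT begins a single base upstream of TTCAAGGACGATCACTCGCT, which fell: it rose from 6.30 ± 0.772 to 36.1 ± 1.30 CPM (SD, n = 2 each), whereas TTCAAGGACGATCACTCGCT fell 5.69-fold, from 275 ± 30.4 to 48.3 ± 10.6 CPM (SD, n = 2 each; edgeR adjusted p = 0.0246). The 21-nt form TTCAAGGACGATCACTCGCTT, the most abundant of the 3, stood at 1832 ± 129 CPM in WT and 708 ± 57.9 CPM in rdr6.1 (SD, n = 2 each) and did not pass (log2 fold change -1.37, SE 0.45, edgeR adjusted p = 0.301). These 2 overlapping forms were chosen after their values were seen, and the fall of TTCAAGGACGATCACTCGCT did not pass without rdr6.1 replicate 1 (edgeR adjusted p = 0.0640), without rdr6.1 replicate 2 (0.0715) or without the abundance filter. The number of risen sequences was 8 without WT replicate 2, 28 without rdr6.1 replicate 2, 77 without rdr6.1 replicate 1 and 215 without WT replicate 1. Without WT replicate 2, CATTGGATAGAATTAAAGGCCT and TCGGATCTTCGGTGATGGATC still passed and the 5 other named rises did not (edgeR adjusted p from 0.0507 to 0.159). ACAGTAGTAGAAGCCTTGCCT also did not pass in DESeq2 (adjusted p = 0.0842), without the filter (edgeR adjusted p = 0.0512), scaled to conserved miRNA (0.134) or without rdr6.1 replicate 1 (0.0824) or 2 (0.0889). CTTCAAGGACGATCACTCGCT and AGAATGCATTGGATGGATG did not pass without the filter (edgeR adjusted p = 0.655 for each). AGAATGCATTGGATGGATG did not pass scaled to conserved miRNA (edgeR adjusted p = 0.0620) or without rdr6.1 replicate 2 (0.0607), nor did TGGGGATATCGGGGTAGACAAC scaled to conserved miRNA (0.0896) or without rdr6.1 replicate 1 (0.0768).

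**Figure D2:**
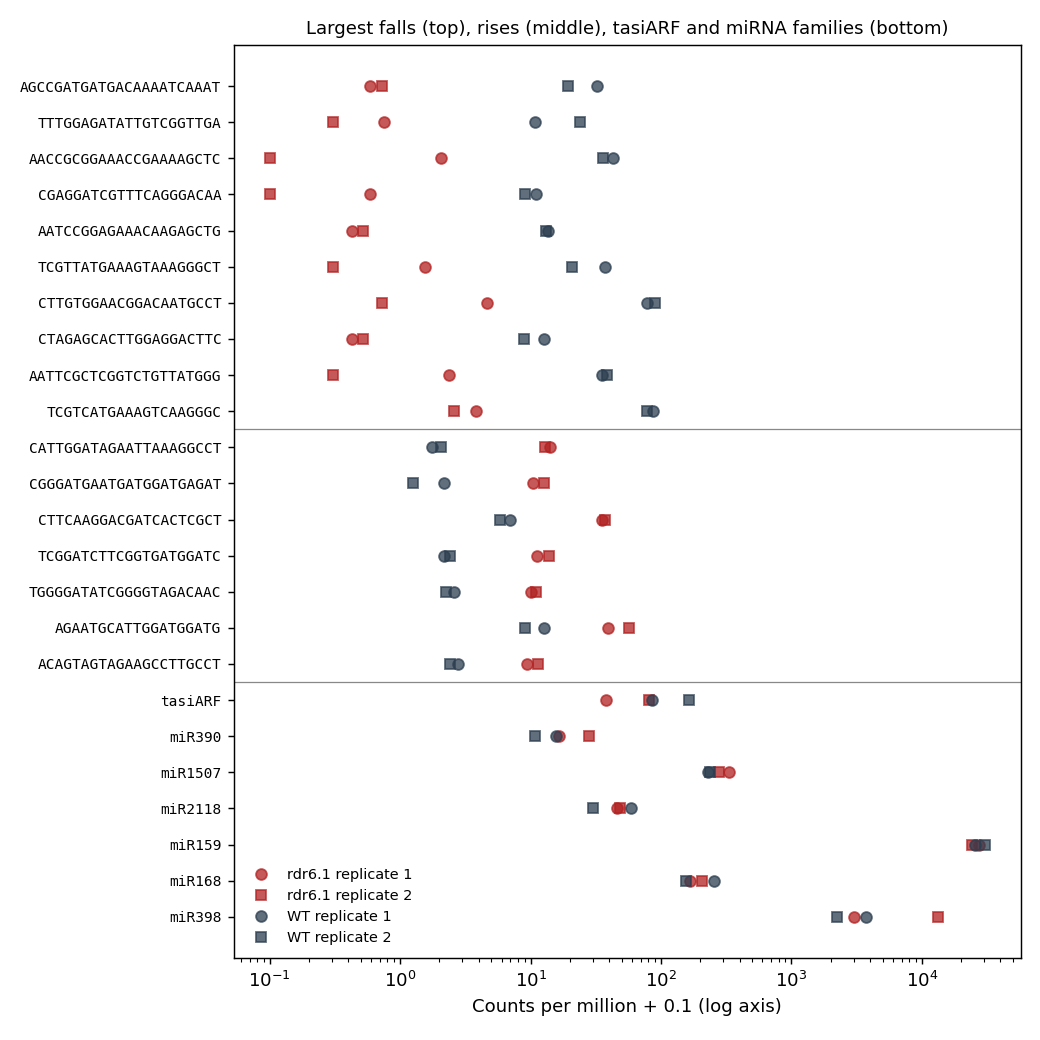
Normalised level in CPM plus 0.1 (log axis) of the 10 largest falls, the 7 rises, tasiARF and 6 miRNA families in each library; circles are replicate 1 and squares replicate 2, red is rdr6.1 and dark blue is WT. TCGTCATGAAAGTCAAGGGC has a mean of 3.12 CPM in rdr6.1 against 82.5 CPM in WT, while the red and dark blue points of miR159 overlap between 24347 and 30369 CPM.

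The second question was whether the known miRNAs and the trans-acting siRNA that targets auxin response factors (tasiARF) differed. None of the 17 families tested passed (edgeR, 0 over all sequences and 0 adjusted over the list alone; 1 at an unadjusted p below 0.05; DESeq2, 0 and 1). Conserved miRNAs were represented by 12 tested families, 6 with a higher and 6 with a lower fitted level in rdr6.1. miR159, which targets GAMYB transcripts, stood at 25784 ± 2031 CPM in rdr6.1 and 27942 ± 3432 CPM in WT (SD, n = 2 each; log2 fold change -0.12, 95% interval -1.36 to 1.13). The fixed mature sequence of miR166, which targets HD-ZIP III transcripts, stood at 87437 ± 17315 and 77610 ± 37303 CPM (SD, n = 2 each, log2 fold change 0.17). A more abundant form, shifted along miR166, was not counted, so these values do not give the level or spread of all miR166 reads. miR168, which targets ARGONAUTE1, and miR162, which targets DICER-LIKE1, had log2 fold changes of -0.14 and 0.29. miR164 had the smallest p of the list and was 2.09-fold higher, at 8.63 ± 0.424 against 4.11 ± 0.235 CPM (SD, n = 2 each), with an edgeR adjusted p of 0.348 over all sequences and 0.308 over the list alone. For the 16 tested conserved miRNA sequences the median log2 fold change was -0.02 and the mean 0.35; camera gave p = 0.165 at the preset correlation and p = 0.411 with an estimated correlation, and fry, which tests whether the sequences move one way on balance, gave p = 0.511. Without rdr6.1 replicate 1, miR160, miR398 and miR408 passed when adjusted over the list alone (edgeR adjusted p = 0.0312, 0.0274 and 0.0081) but not over all sequences, and 6 conserved families changed sign without WT replicate 2.

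Of 5 fixed trigger families of phased siRNA production, 3 were abundant enough to test; miR1509 had 3 reads over all libraries and the fixed sequences of miR2109 were not seen. miR390, the trigger of TAS3 siRNAs, stood at 22.3 ± 8.17 CPM in rdr6.1 and 13.1 ± 3.44 CPM in WT (SD, n = 2 each; log2 fold change 0.77, 95% interval -0.16 to 1.69, edgeR adjusted p = 0.751). The 22-nt triggers of siRNAs from NBS-LRR resistance genes, miR1507 and miR2118, had log2 fold changes of 0.38 (95% interval -0.49 to 1.26) and 0.09 (95% interval -0.86 to 1.04). miR1510, another legume miRNA, stood at 723 ± 100 CPM in rdr6.1 and 673 ± 28.0 CPM in WT (SD, n = 2 each; log2 fold change 0.10). Summed, the triggers had a log2 fold change of 0.36 (SE 0.39, edgeR adjusted p = 0.993).

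tasiARF remained detectable in both rdr6.1 libraries and did not pass the test. Its summed level was 59.4 ± 30.5 CPM in rdr6.1 and 124 ± 55.8 CPM in WT (SD, n = 2 each), a log2 fold change of -1.07 with a 95% interval of -2.20 to 0.06 (edgeR adjusted p = 0.649 over all sequences and 0.313 over the list alone, the 17 families). By library it was 37.8 and 81.0 CPM in rdr6.1 and 85.0 and 164 CPM in WT. Its main form, TTCTTGACCTTGTAAGACCTC, held 204, 353, 367 and 882 reads in rdr6.1 replicates 1 and 2 and WT replicates 1 and 2. The log2 fold change was -1.72 without rdr6.1 replicate 2, -1.47 without WT replicate 1, -0.64 without rdr6.1 replicate 1 and -0.53 without WT replicate 2, with edgeR adjusted p over all sequences of 0.293, 0.105, 0.999 and 0.814. Adjusted over the 4 summed lists alone, it passed without rdr6.1 replicate 2 (edgeR adjusted p = 0.0417) and without WT replicate 1 (0.0194), but not with all libraries (0.246).

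The third question was whether the size profile differed. The 24-nt class held 42.7% ± 3.57 of the reads in rdr6.1 and 42.1% ± 3.29 in WT (SD, n = 2 each). The 21-nt class held 36.6% ± 2.78 and 37.1% ± 5.53 (SD, n = 2 each), a difference smaller than the spread between replicates. Without the 3 most abundant sequences, an alternative chosen after seeing the data, the 21-nt class held 10.7% ± 1.28 in rdr6.1 and 13.0% ± 0.48 in WT (SD, n = 2 each), without overlap. With a library left out, the 21-nt difference over all reads ranged from -4.41 percentage points without WT replicate 2 to 3.42 without WT replicate 1, and the 24-nt difference from -1.85 to 3.20. The 22-nt class held 5.04% ± 0.37 and 4.49% ± 0.18 (SD, n = 2 each), with both rdr6.1 libraries above both WT libraries; the difference of 0.55 percentage points ranged from 0.28 without rdr6.1 replicate 2 to 0.81 without rdr6.1 replicate 1. As a share of distinct sequences the 22-nt class was 5.09% ± 0.53 in rdr6.1 and 4.90% ± 0.11 in WT (SD, n = 2 each), with overlap. In that measure the 21-nt class was 6.19% ± 0.34 in rdr6.1 and 6.91% ± 0.10 in WT (SD, n = 2 each), without overlap. The 25-nt class was 7.65% ± 0.12 and 8.02% ± 0.15 of distinct sequences (SD, n = 2 each), also without overlap. A comparison of 2 libraries with 2 cannot go below p = 0.33 in a two-sided exact permutation test, the value reached by each of these non-overlapping differences. Distinct sequences depend on depth, and in libraries of similar depth the 21-nt class was 5.94% of them (rdr6.1 replicate 1) against 6.98% (WT replicate 2), and 6.43% (rdr6.1 replicate 2) against 6.84% (WT replicate 1).

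**Figure D3:**
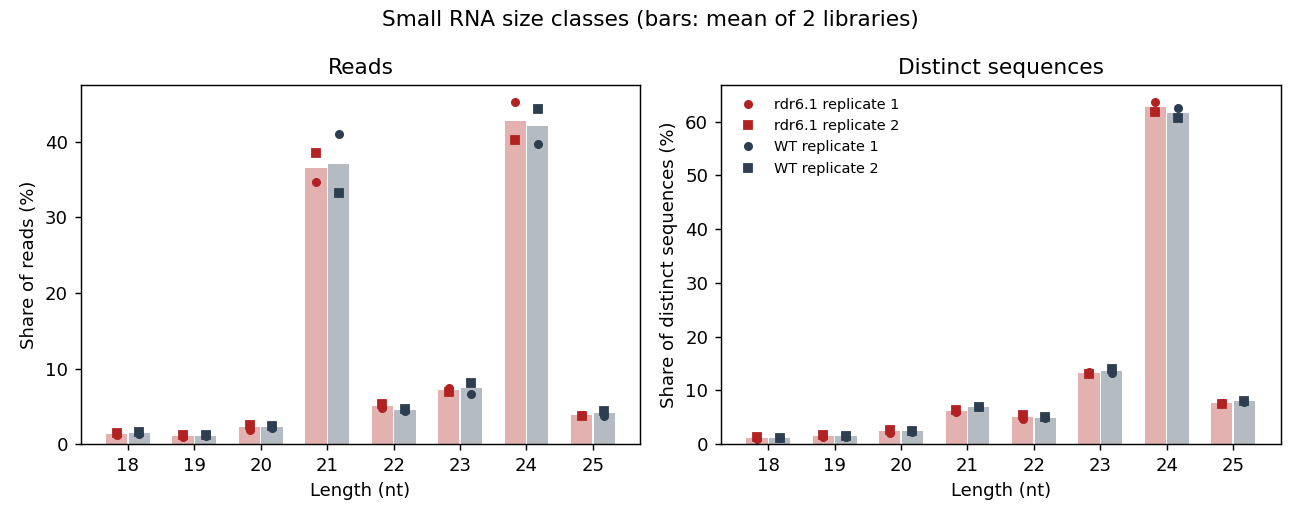
Share of reads (left, percent) and of distinct sequences (right, percent) by length in nt; bars are means of 2 libraries and points are libraries, red for rdr6.1 and dark blue for WT. The 24-nt class is the largest in both panels, at 42.7% and 42.1% of reads, and the 21-nt points of rdr6.1 and WT overlap for reads.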

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

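Falls outnumbered rises under each alternative run, but the number of rises varied widely. Sequences changed numbered 384 in the main analysis (370 fell, 14 rose), 392 with RLE factors, 396 with total counts, 552 scaled to conserved miRNA, 391 with DESeq2 (316 shared with the 384) and 384 with a 2-fold minimum. Without the filter 1267 changed (1005 fell, 262 rose, 303 shared), over 6762531 sequences, and the cause was not tested. Among the named falls, those that lost the call without the filter had a mean log2 CPM of at least 4.28. The named falls that kept it were all less abundant. Among the named rises the call was lost at 4.43 and 4.90, but also at 2.75. With a library left out, 276 to 854 changed, 268 to 639 fell and 8 to 215 rose, highest without WT replicate 1 and lowest without WT replicate 2, and 227 (without WT replicate 2) to 354 (without WT replicate 1) of the 384 were shared; in these fits the lone library is assumed to vary like the other genotype's. With the replicate number as a block, 574 changed: 521 fell and 53 rose, and 383 of the 384 were shared. The deviations of same-numbered libraries correlated at 0.059, and with 2 pairs this does not settle whether they are paired; they also share a primer index. The block changed no call among the 17 named sequences or the fixed lists. Only scaling to conserved miRNA moved the median log2 fold change of all sequences by over 0.1, to -0.18. The reads used for that scaling leave out the more abundant, shifted form of miR166. Of the 17 named sequences, 17 kept their call with RLE factors and total counts, 15 with DESeq2, 14 with miRNA scaling, 10 with no filter, and 12 to 17 with a library left out; no direction turned, though a left-out library moved the fold of 6 by over 1.5 times.

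Among the fixed lists, 0 of 17 families passed over all sequences in edgeR or DESeq2 under each alternative run on them (1 to 5 at an unadjusted p below 0.05). Adjusted over the list alone, 3 passed without rdr6.1 replicate 1 (miR160, miR398 and miR408). With a library left out, uncalled directions turned: the summed conserved miRNAs, with a main log2 fold change of 0.15, ranged from -0.13 to 0.47, and the summed legume miRNA, at 0.10, from -0.05 to 0.22. The log2 fold changes that turned ranged from -0.39 to 0.21 for miR156, -0.24 to 0.01 for miR159, -0.50 to 1.83 for miR160, -0.26 to 0.77 for miR166, -0.49 to 0.16 for miR167, -0.46 to 0.26 for miR168, -0.45 to 0.28 for miR319, -0.59 to 0.15 for miR396, -0.31 to 2.39 for miR408, -0.05 to 0.22 for miR1510 and -0.32 to 0.66 for miR2118. The cause was not tested.

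The 22-nt share, 0.55 percentage points higher in rdr6.1 by reads, was 0.19 higher by distinct sequences and 0.88 higher without the 3 most abundant sequences, an alternative chosen after seeing the data, in which the 21-nt difference was -2.29 points; the causes were not tested. With 2 libraries per genotype at this depth and spread, mostly large changes were recovered: of 50 simulated sequences each, 1, 15, 37 and 42 were recovered at 2-fold, 4-fold, 8-fold and 16-fold, with 6 false calls among all 101. The locus, phasing and genome-matched alternatives were not run, and without rRNA and tRNA fragments was not run either.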

Other observations

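The duplex-partner and resistance-gene tests were written down before their results were seen; the tests of the 22-nt class, of tasiARF and of carried-over RNA were chosen only after the results were seen. Beyond the comparisons above, and chosen after their values were seen, miR398, miR408 and miR160 stood apart in rdr6.1 replicate 2. miR398 was at 13189 CPM there, against 3000 CPM in rdr6.1 replicate 1 and 3726 and 2246 CPM in WT. miR408 was at 119 CPM, against 18.2, 28.6 and 16.4 CPM, miR160 was at 8.33 CPM, against 1.62, 2.49 and 2.14 CPM, and miR397, below the abundance filter, had 27 reads against 6, 1 and 3.

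The fallen sequences more often had a duplex partner than others did. Of 289 fallen 21-nt sequences, 101 had a partner in a WT library whose first 19 nt were the reverse complement of their own, the geometry of a duplex with 2-nt overhangs. That is 34.9% (95% exact binomial interval 29.5% to 40.8%), with overlapping sequences and both strands of a duplex counted as independent, which they are not. Counted in the same way, the share was 13.5% of 289 uncalled 21-nt sequences matched on WT level (Fisher's exact test, two-sided, p = 1.99e-09). This is consistent with cutting from double-stranded precursors, although miRNA hairpins give duplexes of the same kind and no locus was mapped. Whether the sequences came from NBS-LRR genes stayed open: 1 of 327 fallen 21-nt and 22-nt sequences (0.306%, 95% exact binomial interval 0.00774% to 1.69%) encoded one of 5 textbook motifs of NB-ARC and TIR domains, against 0.304% of 3620 uncalled ones (p = 1, Fisher's exact test, two-sided), too few hits to decide.

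A candidate pattern is a rise of the 22-nt class in rdr6.1, where 71.1% of 1638 tested sequences had a positive log2 fold change, with a median of 0.43 against 0.00 for 24 nt. The 18-nt class also had a median above 0, at 0.29 over 272 sequences, 62.1% of them positive (adjusted p = 0.0232 in camera at the preset correlation, 0.668 with an estimated correlation and 0.619 in fry). That shift rested on rdr6.1 replicate 2, where uncalled 18-nt sequences had a median log2 deviation from their mean over libraries of 0.392, against -0.149 in rdr6.1 replicate 1 and -0.014 and -0.262 in WT; the same library was highest at 19 nt (0.256) and 20 nt (0.201). Size selection would move neighbouring lengths too. Relative to the mean of uncalled 21 nt and 23 nt, 22 nt stood at 0.18 and 0.39 in the rdr6.1 libraries on the log2 scale. In the WT libraries it stood at -0.33 and -0.31, so the rdr6.1 minus WT difference was 0.60, with a pooled SD of 0.10. Part of this is the fall of uncalled 21-nt sequences, whose difference was -0.251, against 0.441 for 22 nt and -0.072 for 23 nt. Neither neighbour rose with 22 nt, but a bias of single libraries by length is not excluded. Without rdr6.1 replicate 2 the 22-nt median went from 0.43 to 0.24, against -0.01 for all sequences. That library alone therefore does not account for all of the rise in this median, and other omissions were not examined for it. By reads, both rdr6.1 libraries had a higher 22-nt share than both WT libraries. By distinct sequences, rdr6.1 replicate 1 held 4.71%, below 4.82% and 4.98% in WT, so on that measure the higher mean rested on rdr6.1 replicate 2. The median was 0.49 over 1374 of the 22-nt sequences, those that do not extend an equally or more abundant 21-nt sequence. These can still extend a rarer 21-nt sequence, so addition of a base to 21-nt sequences is not excluded. Genotype stays open: for 22 nt, camera gave an adjusted p of 1.25e-06 at the preset correlation but 0.451 with an estimated correlation. In fry the adjusted p was 0.574. Genotype and sequencing lane cannot be told apart in this design.

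tasiARF kept 30.4% and 65.1% of its WT mean in rdr6.1 replicates 1 and 2, or 23.1% and 49.4% of its higher WT library. The fallen sequences were selected for a low level in rdr6.1, so a lower share in them is expected and says nothing of tasiARF; they can only bound carried-over WT RNA, which would leave every sequence at least at one common share. To keep selection in a library from lowering the share measured there, sequences that fell in the fit without that library were used, with WT the same in both steps. Their upper quartile was 15.3% in replicate 1 (285 sequences) and 13.2% in replicate 2 (450 sequences), which argues against carry-over as the whole source of the remaining tasiARF. For the 370 fallen sequences, medians of 9.06% and 6.04% were left. For 62 of them with at least 100 reads in each WT library, the variance of the log2 kept share was compared with an expected variance. The expected variance allowed for a common share, counting noise and the spread between WT libraries. The observed variance was 1.78 times the expected in replicate 1 (95% bootstrap interval 1.11 to 2.76) and 3.47 times in replicate 2 (2.23 to 4.54). The expected variance takes reads as independent, although PCR copies are counted as reads. The 62 sequences were also called on these same libraries, which can alter both the observed and the expected variance. The excess argues against carry-over at a single share as the whole source only under 2 conditions. Such copies must add little noise at the low rdr6.1 counts, and the selection must have altered the variances little. Those conditions and other sources were not tested.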
